A study of Homo sapiens with 15 samples.

How the data were processed

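RNA was measured by strand-specific sequencing of ribosomal RNA-depleted total RNA in 15 libraries from 2 human lymphoma cell lines, Z-138 and OCI-Ly10. Per the labels' protocols, cells in logarithmic growth received SR-3029, an inhibitor of casein kinase 1 delta, or the control treatment for 3 h, RNA was purified on Qiagen RNeasy columns, and libraries were made with a NEBNext Ultra Directional kit and sequenced on a NextSeq instrument. The labels give 5 groups of 3 libraries: Z-138 control, Z-138 at 1 µM, Z-138 at 3 µM, OCI-Ly10 control and OCI-Ly10 at 1 µM. The control is labelled only as a control, and the vehicle is not given in the sources used here. Nothing in the labels says that the replicates of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

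The authors deposited whole-number read counts per gene for each library, with no normalization, over 58219 genes, and no line of the files lacked a gene. Per the submitters' processing notes, STAR, DESeq2 and limma were used, without versions or roles; the counting program, genome build, annotation and strand setting are not given in the sources used here. By identifier, 57881 of the 58219 genes (99.4%) matched GENCODE release 29 on GRCh38, and 56087 of those (96.9%) had the same start and end there. Coordinates are the deposited ones, and symbols and gene types were taken from that release. The remaining 338 genes had no symbol.

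How reads were assigned to overlapping genes was checked on the counts. Of 705 genes whose exons are wholly covered by exons of a gene on the opposite strand, 0 had a count in any library, as had 0 of 1029 genes wholly covered on the same strand. Among 41993 genes with no such overlap, 26170 (62.3%) had counts. The deposited counts thus leave out reads over 2 genes on either strand, as counting without strand does, although the kit marks strand. A gene and its antisense partner can therefore not be told apart in these counts, and genes with a large exon overlap are measured on part of their exons. Genes with near-identical copies (small nuclear RNAs, replication histones, ribosomal protein genes with pseudogenes, mitochondrial genes with nuclear copies) are uncertain in the same way.

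Library totals ran from 5110390 counts (OCI-Ly10 control replicate 2) to 13510179 (Z-138 control replicate 2). Pairs of replicates were compared by a chi-square of their counts, and the lowest chi-square per degree of freedom was 1.59, above the value of 1 that sampling alone would give, so no library was treated as a copy of another. Intervals given for ratios of few counts are exact 95% counting intervals over the summed group counts. Where a group had 0 counts, the floor was 3 counts over the group, and the fold is written as at least that size. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

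Genes were tested with edgeR 4.0.16 in R 4.3.3. The counts of all 15 libraries entered a single quasi-likelihood fit with 1 coefficient per group, TMM factors, and the filterByExpr filter with a minimum count of 10, which kept 17312 genes. The common biological coefficient of variation was 0.0543. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, and p-values are two-sided. The standard error of a log2 fold change is its size divided by the square root of its F statistic. Levels are counts-per-million (CPM) on TMM-scaled library sizes. Summed levels of cell type markers and ratios of few counts use the unscaled library totals instead. The 6 comparisons were Z-138 at 1 µM and at 3 µM against control, Z-138 at 3 µM against 1 µM, OCI-Ly10 at 1 µM against control, the difference of the 1 µM effect between the lines (OCI-Ly10 minus Z-138), and the mean 1 µM effect over both lines.

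Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the 30 lists with at least 5 tested members. They were: casein kinase 1 family, circadian clock, Wnt targets, MYC targets, ribosome biogenesis, translation initiation factors, cytosolic ribosomal proteins, immediate early genes, P-TEFb regulation, NF-κB targets, interferon response, ATF4 stress response, unfolded protein response, heat shock, p53 targets, BCL2 family, G1/S and E2F targets, G2/M and mitosis, replication histones, cholesterol synthesis, cholesterol efflux, glycolysis and hypoxia, substrates of nonsense-mediated decay with small nucleolar RNA hosts, B-cell receptor signalling, B-cell transcription factors, proteasome, nuclear oxidative phosphorylation, mitochondrially encoded genes, abundant non-coding RNAs, and T and NK cell markers. Myeloid markers and epithelial and stromal markers had fewer than 5 tested members and are given as levels. A list is called at an adjusted p under 0.05.

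The groups, the comparisons, the main tests, the lists, most of the alternatives and the rule for naming genes were fixed before the data were examined. For each comparison of a treated group with its control, the rule names the 8 called genes with the largest rise and the 8 with the largest fall among named genes that are not pseudogenes, with a mean of at least 5 CPM and all 3 treated libraries on one side of all 3 controls. It adds up to 4 members, by smallest p, of each called list and of 8 lists chosen in advance, lowest-ranked left out first for length. For the dose comparison and the line difference it names the 5 largest in each direction, and in every comparison it names CSNK1D, CSNK1E, CSNK1A1, PER1, PER2, AXIN2, MYC, CCND1, MCL1, BCL2, HEXIM1, EIF4E and EIF4EBP1. A further 8 genes served as an identity check of the lines.

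The alternatives were DESeq2 size factors, library size without a composition factor, library sizes and TMM over protein-coding genes, no filter, a stricter filter (at least 5 CPM in at least 3 libraries, 12689 genes), the DESeq2 1.42.0 Wald test, limma-voom, fits of the compared groups alone, a replicate block, a minimum absolute log2 fold change of 1, and leaving out each library in turn. For lists they were an estimated correlation, fry, the replicate block and leaving out each library. Scaling to the geometric mean of the 13 mitochondrially encoded mRNAs takes them as unchanged. It and thinning every library to the smallest total were added after the data were seen. No spike-in was used here, so every fold change is relative to the rest of the library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for tables and plots.

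The gene test was checked on counts simulated for all 15 libraries from the control means of each line and the library totals, over 14722 genes. For Z-138 at 1 µM against control it recovered 36.7% of genes changed 1.25-fold, 67.4% of those changed 1.5-fold, 84.0% of those changed 2-fold and 95.9% of those changed 4-fold, and called 0.0826% of the unchanged genes. Since 14528 of these genes were left unchanged, the check does not cover a change in most genes or its effect on the scaling.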

Results

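Gene expression was compared in Z-138, a mantle cell lymphoma line, and OCI-Ly10, a diffuse large B-cell lymphoma line, after 3 h of SR-3029, an inhibitor of casein kinase 1 delta (CK1δ), a protein kinase encoded by CSNK1D. Z-138 cells received 1 µM or 3 µM of the inhibitor and OCI-Ly10 cells received 1 µM, each with its own control, in 5 groups of 3 libraries. The series concerns a role of CK1δ in translation initiation, so genes of the translation machinery were described beside those of the kinase family, the cell cycle and the B-cell programme.

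Total counts per library were 12605633 to 13510179 in Z-138 controls, 7110343 to 8205786 at 1 µM and 7480378 to 8980931 at 3 µM. In OCI-Ly10 they were 5110390 to 10797096 in controls and 5798264 to 8296070 at 1 µM. Levels of lineage genes in the control libraries differed between the lines. CCND1, the cyclin D1 gene activated in mantle cell lymphoma, stood at 2730 ± 134 CPM (SD, n = 3) in Z-138 and 2.87 ± 0.27 CPM in OCI-Ly10. SOX11, a transcription factor expressed in mantle cell lymphoma, stood at 290 ± 6.0 and 0.312 ± 0.321 CPM. BCL6, a germinal centre repressor, stood at 1.5 ± 0.50 CPM in Z-138 and 104 ± 4.81 CPM in OCI-Ly10. The B-cell genes MS4A1 (508 and 724 CPM), CD79B (135 and 150 CPM), PAX5 (499 and 362 CPM) and IRF4 (609 and 1265 CPM) were expressed in both.

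Treated libraries held a smaller share of protein-coding counts and a larger share of non-coding ones. Protein-coding genes took 96.2% ± 0.07 of the counts in Z-138 controls (SD, n = 3), 91.1% ± 0.36 at 1 µM and 91.6% ± 0.19 at 3 µM, and in OCI-Ly10 96.1% ± 0.06 and 92.7% ± 0.09. Long intergenic RNAs went from 1.87% to 5.16% and 4.79% in Z-138 and from 1.23% to 3.05% in OCI-Ly10, most of it MALAT1, a nuclear speckle RNA, which alone took 1.54%, 4.09% and 3.66% in Z-138 and 0.644% and 1.90% in OCI-Ly10. Genes annotated as antisense went from 0.309% to 0.982% and 0.984% in Z-138 and from 0.476% to 0.941% in OCI-Ly10. The mitochondrial share was 2.76%, 4.44% and 5.02% in Z-138 and 2.05% and 3.19% in OCI-Ly10. Markers of T and NK cells summed to 40 CPM in Z-138 controls and 43.0 CPM in OCI-Ly10 controls, and to between 48.5 and 54.5 CPM in the treated groups. Myeloid markers summed to at most 11.6 CPM and epithelial and stromal markers to at most 59.6 CPM in any group.

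**Figure D1:**
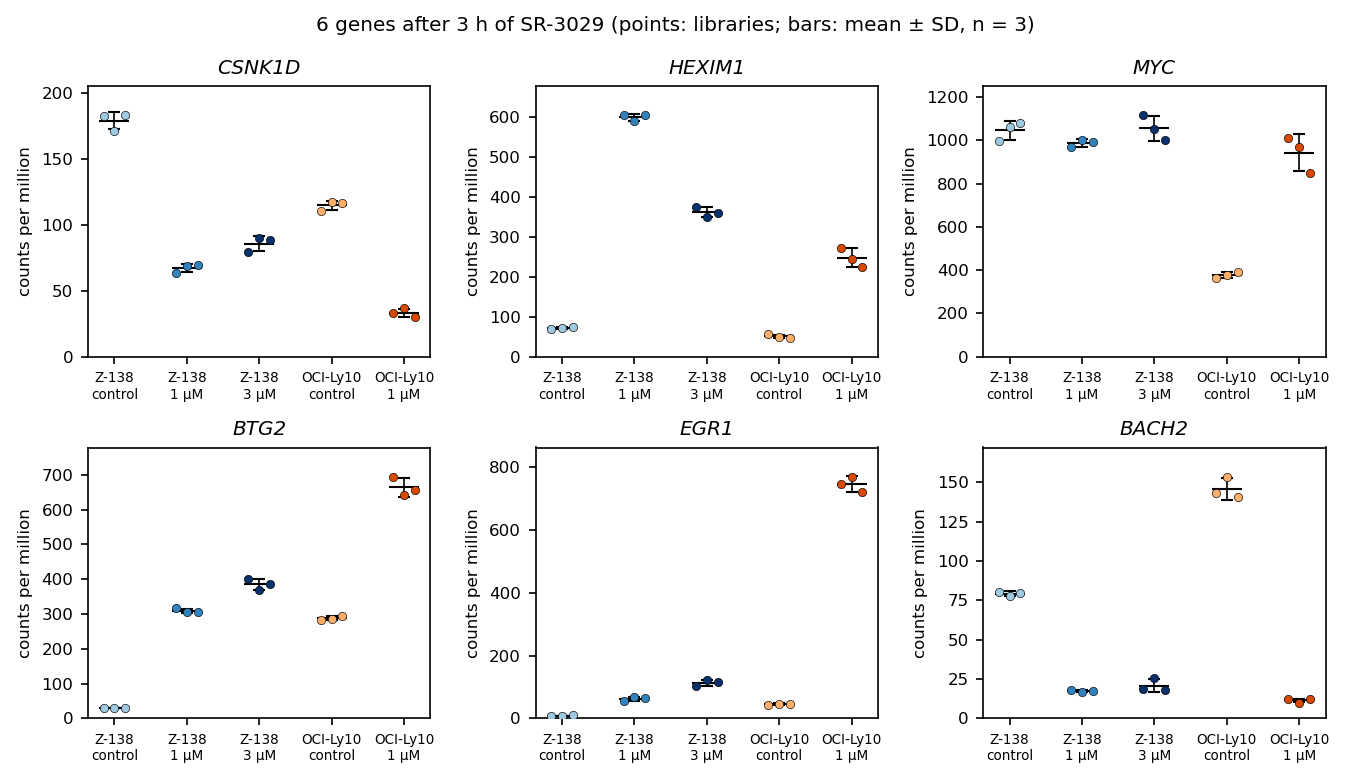
CPM (vertical axes, starting at 0) of CSNK1D, HEXIM1, MYC, BTG2, EGR1 and BACH2 in the 5 groups (horizontal axes), with a point per library and bars for the mean ± SD of 3 libraries. CSNK1D and BACH2 lay lower, and HEXIM1, BTG2 and EGR1 higher, in every treated library than in the controls of the same line, while MYC lay higher than all controls of its line in every treated library of OCI-Ly10 and in 1 of the 6 of Z-138.

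The first comparison asks what 3 h of 1 µM SR-3029 did in Z-138. The gene of the inhibitor's target, CSNK1D, fell from 179 ± 6.57 to 67.3 ± 2.99 CPM (SD, n = 3), a log2 fold change of −1.41 ± 0.07 (SE; adjusted p = 1.7e-24). CSNK1D (ENSG00000141551.14) lies on chromosome 17 from 82239023 to 82273731 (GRCh38, protein-coding), and exons of another gene on the opposite strand cover 16.8% of its exons. Of the 6 tested casein kinase 1 genes 4 fell and 1 rose. CSNK1G1 fell by 2.35 ± 0.11 on the log2 scale, CSNK1A1 fell by 0.50 ± 0.06. CSNK1E, the closest relative of CSNK1D, rose by 0.30 ± 0.07 (adjusted p = 0.00014), but stood at −0.53 under scaling to the mitochondrial mRNAs. As a list the family did not pass the test (adjusted p = 0.080). Among circadian clock genes, whose PER proteins are CK1δ substrates, 5 of 13 rose and 6 fell (adjusted p = 0.99): PER2 fell by 2.09 ± 0.10, while the repressors BHLHE40 and NFIL3 rose by 2.30 ± 0.07 and 2.17 ± 0.09. PER1 showed a log2 fold change of 0.02 ± 0.09 (adjusted p = 0.88), but was called higher under protein-coding scaling (0.26) and lower under mitochondrial scaling (−0.81). Wnt targets went both ways, with 3 of 12 higher and 3 lower (adjusted p = 0.75, with a median of −0.07 and a mean of 0.44). ZNRF3, a ubiquitin ligase that removes Wnt receptors, fell by 3.38 ± 0.16, FZD7, such a receptor, rose by 2.69 ± 0.20, and AXIN2 stood at −0.17 ± 0.17 (adjusted p = 0.37), a fall that was called under mitochondrial scaling alone (−1.01).

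Immediate early genes, which respond within minutes to hours to growth factors and stress, rose together. Of 43 tested members 36 rose and 3 fell, with a median log2 fold change of 2.11 (camera adjusted p = 4.8e-16, and adjusted p = 0.026 with an estimated correlation). BTG2, an antiproliferative gene, went from 29.0 ± 0.40 to 310 ± 5.68 CPM (10.7-fold, adjusted p = 5.4e-40), and IER2 rose 8.74-fold, with 30.8% of its exons under those of an opposite-strand gene. Genes around P-TEFb, the kinase that releases paused RNA polymerase II, rose in 7 of 10 cases and fell in 3 (adjusted p = 0.0485, and adjusted p = 0.19 with an estimated correlation). HEXIM1, which inhibits P-TEFb together with the 7SK RNA, went from 72.1 ± 2.41 to 598 ± 8.97 CPM, a log2 fold change of 3.05 ± 0.06 (adjusted p = 5.1e-38). HEXIM1 (ENSG00000186834.3) lies on chromosome 17 from 45148502 to 45152101. SERTAD1, a transcriptional co-regulator, rose by 3.43 ± 0.12.

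Within the translation machinery, ribosomal protein mRNAs and the genes that build ribosomes moved apart. Of 79 cytosolic ribosomal protein genes 78 rose, with a median log2 fold change of 0.50 that became −0.34 under mitochondrial scaling (adjusted p = 3.2e-10, and adjusted p = 0.48 with an estimated correlation). RPL41 and RPL36A rose by 2.03 ± 0.09 and 1.80 ± 0.09. Of 56 ribosome biogenesis genes 46 fell and 4 rose, with a median of −0.67 (adjusted p = 5.6e-09, and adjusted p = 0.017 with an estimated correlation). They included RRN3, an initiation factor of RNA polymerase I, which fell by 1.76 ± 0.07, and NOL11, a factor of ribosomal RNA processing, which fell by 1.62 ± 0.06. MYC targets fell in 22 of 39 cases and rose in 9 (median −0.30, adjusted p = 0.039, and adjusted p = 0.48 with an estimated correlation). Among them POLR1B, a subunit of RNA polymerase I, fell by 2.17 ± 0.08 and WDR43, a factor of pre-ribosomal RNA processing, fell by 1.60 ± 0.06. MYC itself, at 987 ± 17 against 1045 ± 44.7 CPM, did not pass the test (log2 fold change −0.08 ± 0.06, adjusted p = 0.17). The MYC result depends on the scaling, with a called fall under mitochondrial scaling (−0.92, adjusted p = 2.8e-08) and a called rise under protein-coding scaling (0.16, adjusted p = 0.0070). Translation initiation factors went both ways, with 15 of 48 higher and 24 lower (adjusted p = 0.72, and a median of −0.12 that became 0.12 under protein-coding scaling). EIF4E, the cap-binding protein, fell by 0.52 ± 0.08 (adjusted p = 1.6e-07), its inhibitor EIF4EBP1 fell by 0.34 ± 0.10 (adjusted p = 0.0023) and EIF5 fell by 0.87 ± 0.05. The helicase gene EIF4A1, counted throughout on unshared exons (48.6% are shared), rose by 1.60 ± 0.11. The EIF4EBP1 call ended under protein-coding scaling (−0.09), the stricter filter (−0.16), the DESeq2 Wald test (−0.23) and thinning (−0.22).

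Cell cycle genes fell. Of 51 genes of G2/M and mitosis 46 fell and 2 rose, with a median of −0.80 (adjusted p = 3.6e-12, and adjusted p = 0.041 with an estimated correlation). Of 50 genes of G1/S and E2F targets 36 fell and 4 rose, with a median of −0.53 (adjusted p = 1.3e-06, and adjusted p = 0.026 with an estimated correlation). CCNF, the cyclin F gene, went from 220 ± 1.40 to 30.9 ± 1.57 CPM. E2F7, an E2F family repressor, fell by 3.02 ± 0.08, EXO1, a DNA repair exonuclease, by −2.07 ± 0.07, and CDC25A, a phosphatase that activates cyclin-dependent kinases, by −1.96 ± 0.07. Replication histone genes were higher in 29 of 43 cases and lower in 1, with a median of 0.40 that became −0.43 under mitochondrial scaling (adjusted p = 0.0015, and adjusted p = 0.67 with an estimated correlation). HIST1H2BG and HIST1H3A rose by 1.01 ± 0.06 and 1.08 ± 0.07, calls that ended under that scaling (0.18 and 0.25). CCND1 stood at 2664 ± 147 against 2730 ± 134 CPM (log2 fold change −0.04 ± 0.08, adjusted p = 0.72). It was called lower under mitochondrial scaling (−0.87, adjusted p = 8.1e-08) and higher under protein-coding scaling (0.21, adjusted p = 0.021).

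B-cell transcription factor genes fell in 14 of 24 cases and rose in 4, with a median of −0.64 (adjusted p = 0.0059, and adjusted p = 0.059 with an estimated correlation). IKZF3, the Aiolos gene, fell from 482 ± 1.90 to 120 ± 3.95 CPM, and IRF4, a factor of B-cell and plasma cell identity, fell by 1.53 ± 0.05. Genes of the unfolded protein response fell in 18 of 29 cases and rose in 3 (median −0.36, adjusted p = 0.037, and adjusted p = 0.19 with an estimated correlation). CREB3L2, a factor anchored in the endoplasmic reticulum, fell by 1.22 ± 0.06 and DNAJC3, a chaperone of that compartment, by −1.38 ± 0.07. NF-κB targets were split, 10 of 33 higher and 10 lower (adjusted p = 0.99, with a median of 0.00, a mean of 0.30 and a test pointing down); REL, an NF-κB subunit gene with 50.7% of its exons shared, fell by 2.20 ± 0.09. Of the survival genes, BCL2 rose from 266 ± 3.37 to 535 ± 16.3 CPM (log2 fold change 1.01 ± 0.05), a call that ended under mitochondrial scaling (0.17), and MCL1 rose by 0.40 ± 0.05 but fell by 0.44 under that scaling.

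Several classes of abundant or non-coding RNA rose as well. Of 9 abundant non-coding RNAs 8 rose (median 1.92, adjusted p = 8.7e-05, and adjusted p = 0.18 with an estimated correlation). NEAT1, the RNA of paraspeckles, went from 337 ± 28.9 to 2059 ± 47.0 CPM, and MALAT1 rose 2.53-fold. Substrates of nonsense-mediated decay and small nucleolar RNA hosts rose in 23 of 40 cases and fell in 13, with a median of 0.48 that became −0.36 under mitochondrial scaling (adjusted p = 0.039, and adjusted p = 0.46 with an estimated correlation). SNHG3, such a host gene, rose 4.04-fold, and GADD45A, a stress gene, 13.7-fold. Of 15 mitochondrially encoded genes 13 rose and 2 fell, with a median of 0.72 (adjusted p = 0.0059, and adjusted p = 0.58 with an estimated correlation). Mitochondrial scaling is built from 13 of these genes and so cannot test them. MT-ATP8, which shares 22.2% of its length with another gene, rose by 1.99 ± 0.11 and MT-ND4L by 1.17 ± 0.09. Nuclear genes of oxidative phosphorylation rose in 33 of 47 cases and fell in 5, with a median of 0.27 that became −0.57 under mitochondrial scaling (adjusted p = 0.017, and adjusted p = 0.58 with an estimated correlation). NDUFV2, a complex I subunit with 28.4% of its exons shared, rose by 1.74 ± 0.11, and COX7B, of complex IV, by 0.57 ± 0.06, which became −0.26 under that scaling.

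The other lists did not pass the test in this comparison. Higher and lower members numbered 7 and 5 of 34 for interferon response, 13 and 13 of 34 for the ATF4 stress response, 12 and 8 of 24 for heat shock, 16 and 11 of 32 for p53 targets, and 9 and 3 of 15 for the BCL2 family. They numbered 5 and 12 of 24 for cholesterol synthesis, 2 and 4 of 9 for cholesterol efflux, 14 and 9 of 31 for glycolysis and hypoxia, 8 and 13 of 27 for B-cell receptor signalling, and 8 and 13 of 31 for the proteasome. Of 5 tested T and NK cell markers 4 rose (adjusted p = 0.39). The ATF4 list had a median of −0.05 and a mean of 0.45, and the interferon list a median of −0.07 with the test pointing up. Adjusted over the list alone, the number of called members was the same as over all genes in all 30 lists except G2/M and mitosis (49 against 48), Wnt targets (5 against 6), interferon response (11 against 12) and the proteasome (20 against 21).

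The genes with the largest rises were near silent in the control. NAALADL1, a peptidase gene (ENSG00000168060.15, chromosome 11, 65044818 to 65058549), had 328 counts over the 3 treated libraries and 1 over the 3 controls, a ratio of 563 with a 95% counting interval of 100 to 2.23e+04. LINC01953 had 256 against 3 counts, a ratio of 146 (49.6 to 715). LINC02028, the small heat shock protein gene HSPB7, the U5 small nuclear RNA genes RNU5B-1 and RNU5A-1, the endosomal protein gene PHETA2 and ADAMTSL4-AS1 rose by 5.33 to 6.57 on the log2 scale. The U5 genes have near-identical copies, and exons of the opposite strand cover 28.1% of those of ADAMTSL4-AS1. The largest falls were in BAMBI, a TGF-β pseudoreceptor (ENSG00000095739.10, chromosome 10, 28677342 to 28682939; 22.7 ± 3.41 to 0.705 ± 0.120 CPM, 31.8-fold lower) and KLHL26, a Kelch family gene (24-fold lower). Next were MAP3K14, the NF-κB-inducing kinase (15.1-fold lower) and KLHDC10, another Kelch family gene (12.9-fold lower). They were followed by KIAA0355, PHLPP2, a phosphatase of AKT, GTF2E1, a subunit of the general transcription factor TFIIE, and KIAA0040, the last 4 between 10.6-fold and 11.6-fold lower.

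In all, 12861 of 17312 tested genes passed the threshold, 6491 higher and 6370 lower, and 7272 also changed at least 2-fold. Among protein-coding genes 3460 were higher and 5910 lower of 12644. Among long intergenic RNA genes 718 were higher and 65 lower of 1034, and among antisense genes 1017 and 115 of 1402. By genomic span, 59.6% of the shortest of 5 equal groups of protein-coding genes rose and 15.4% fell, against 13.2% and 65.3% of group 4 and 13.4% and 56.7% of the longest. The split depends on the scaling: 50.5% of the calls were higher under TMM, 61.5% under protein-coding scaling and 26.4% under mitochondrial scaling. The median of all tested genes, those without counts in the line included, was 0.00 in both Z-138 comparisons and 0.06 in OCI-Ly10 under TMM. It was 0.24, 0.23 and 0.16 (Z-138 1 µM, Z-138 3 µM, OCI-Ly10) under protein-coding scaling and −0.78, −0.93 and −0.63 under mitochondrial scaling, so each direction holds relative to the bulk of the genes.

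**Figure D2:**
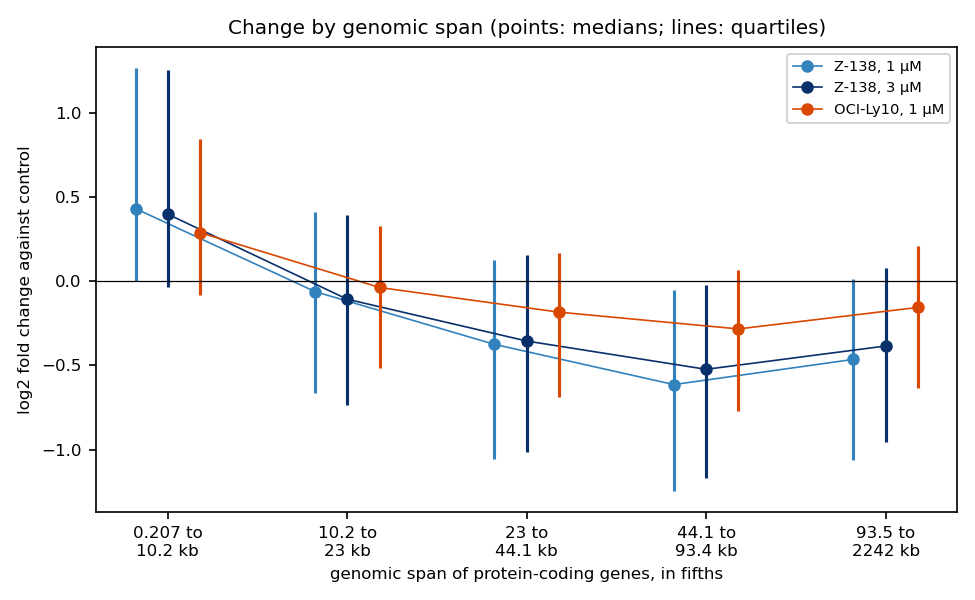
Log2 fold change against control (vertical axis, TMM scaling) of protein-coding genes in 5 equal groups by genomic span in kb (horizontal axis), with medians as points and quartiles as lines, for Z-138 at 1 µM and 3 µM and OCI-Ly10 at 1 µM. In Z-138 at 1 µM the median went from 0.43 in the shortest group to −0.61 in the fourth and −0.46 in the longest, and the position of 0 moves with the scaling.

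The next comparison asks what the higher dose, 3 µM, did in Z-138 against the same controls. CSNK1D fell from 179 ± 6.57 to 85.7 ± 5.75 CPM (log2 fold change −1.06 ± 0.06, adjusted p = 2.2e-20), CSNK1G3 fell by 1.89 ± 0.09 and CSNK1A1 fell by 0.43 ± 0.06, while CSNK1E stood at −0.11 ± 0.07 (adjusted p = 0.15) and was called under mitochondrial scaling (−1.10). Of the 6 tested family members 4 fell and 1 rose (list adjusted p = 0.051). Immediate early genes rose in 34 of 43 cases and fell in 4 (median 1.75, adjusted p = 1.35e-13, and adjusted p = 0.042 with an estimated correlation). EGR1, a zinc finger transcription factor, went from 7.95 ± 0.90 to 113 ± 10.2 CPM, and BTG2 rose 13.3-fold. HEXIM1 rose by 2.33 ± 0.06, within a P-TEFb list in which 7 of 10 rose and 3 fell and that did not pass the test (adjusted p = 0.083).

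Ribosome biogenesis genes fell in 46 of 56 cases and rose in 3 (median −0.60, adjusted p = 1.2e-07, and adjusted p = 0.042 with an estimated correlation), with NOL11 at −1.46 ± 0.06. Ribosomal protein genes rose in 77 of 79 cases and fell in 1, with a median of 0.39 that became −0.58 under mitochondrial scaling (adjusted p = 9.2e-08, and adjusted p = 0.54 with an estimated correlation), and RPL36A rose by 1.99 ± 0.09. MYC targets fell in 22 of 39 cases and rose in 7, with a median of −0.22 that became 0.03 under protein-coding scaling (adjusted p = 0.029, and adjusted p = 0.39 with an estimated correlation); POLR1B fell by 2.21 ± 0.08. Translation initiation factors were higher in 16 of 48 and lower in 24 (adjusted p = 0.71). EIF5 fell by 0.94 ± 0.05, EIF4E by −0.52 ± 0.08 and EIF4EBP1 by −0.28 ± 0.10 (adjusted p = 0.0093). EIF4A1 (unshared exons) rose by 1.71 ± 0.11. The EIF4EBP1 call ended in 6 other settings (−0.20 to −0.04) and without control replicate 3 (−0.21) or 3 µM replicate 1 (−0.23).

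G2/M and mitosis genes fell in 44 of 51 cases and rose in 1 (median −0.83, adjusted p = 7.7e-12, and adjusted p = 0.042 with an estimated correlation). G1/S and E2F genes fell in 36 of 50 and rose in 3 (median −0.51, adjusted p = 3.6e-06, and adjusted p = 0.042 with an estimated correlation). CCNF fell by 2.51 ± 0.07 and E2F7 fell by 2.34 ± 0.08. Replication histones rose in 31 of 43 cases and fell in 3, with a median of 0.57 that became −0.39 under mitochondrial scaling (adjusted p = 0.00011, and adjusted p = 0.62 with an estimated correlation). HIST1H2BG rose by 1.08 ± 0.06, a call that ended under that scaling (0.11). B-cell transcription factors fell in 15 of 24 cases and rose in 5 (median −0.77, adjusted p = 0.0043, and adjusted p = 0.042 with an estimated correlation), with IRF4 going from 609 ± 4.60 to 160 ± 2.42 CPM. The unfolded protein response fell in 20 of 29 cases and rose in 1 (median −0.30, adjusted p = 0.0105, and adjusted p = 0.16 with an estimated correlation), with DNAJC3 at −1.31 ± 0.07. Abundant non-coding RNAs rose in 8 of 9 cases and fell in 1 (median 1.38, adjusted p = 0.00031, and adjusted p = 0.17 with an estimated correlation), NEAT1 8.78-fold.

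Mitochondrially encoded genes rose in 13 of 15 cases and fell in 2, with a median of 0.94 (adjusted p = 0.0012, and adjusted p = 0.54 with an estimated correlation), MT-ATP8 by 2.09 ± 0.11. Nuclear oxidative phosphorylation genes, higher in 23 of 47 cases and lower in 6, did not pass the test (adjusted p = 0.095). Decay substrates and small nucleolar RNA hosts rose in 23 of 40 cases and fell in 14, with a median of 0.35 that became −0.64 under mitochondrial scaling (adjusted p = 0.042, and adjusted p = 0.39 with an estimated correlation), with SNHG3 4.05-fold higher. PER2 fell by 1.86 ± 0.09 and BHLHE40 rose by 1.98 ± 0.07, and the clock list did not pass the test (5 of 13 higher, 6 lower, adjusted p = 0.71). Among Wnt targets, 4 of 12 higher and 4 lower (adjusted p = 0.83), ZNRF3 fell by 3.10 ± 0.15 and AXIN2 fell from 8.74 ± 0.33 to 2.76 ± 0.22 CPM (adjusted p = 3.8e-10). BCL2 rose by 0.67 ± 0.05, which became −0.32 under mitochondrial scaling. PER1 (0.00 ± 0.09, adjusted p = 1.0), MYC (0.02 ± 0.06, adjusted p = 0.82), CCND1 (0.04 ± 0.08, adjusted p = 0.66) and MCL1 (0.08 ± 0.05, adjusted p = 0.19) did not pass the test. Under mitochondrial scaling all 4 were called lower (−0.97, −0.96, −0.93 and −0.91). Other settings called them higher, MCL1 in 7 (0.14 to 0.32), MYC in 4 (0.13 to 0.26), CCND1 in 3 (0.11 to 0.29) and PER1 under protein-coding scaling (0.24). Adjusted over the list alone, counts of called members equalled those over all genes in every list named in these 3 paragraphs except translation initiation (41 against 40).

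NAALADL1 had 581 counts over the 3 treated libraries against 1 (ratio 907, 95% counting interval 162 to 3.59e+04). NALT1, an RNA antisense to NOTCH1, had 314 against 2 (ratio 245, 67.3 to 2032), and GDF15, a stress-induced cytokine gene, 390 against 3 (ratio 203, 68.9 to 988). LINC02028, WDR38, ADAMTSL4-AS1, AIFM3 and RNU5B-1 rose by 5.70 to 6.77 on the log2 scale. BAMBI (22.6-fold), MAP3K14 (17.1-fold), KLHL26 (16.9-fold) and GTF2E1 (15.2-fold) were again among the largest falls, with RBAK, ZSCAN20 and ZNF420, zinc finger genes, and TEF, a clock-controlled factor, 11.4-fold to 11.9-fold lower. The calls numbered 12765 of 17312, 6387 higher and 6378 lower, and 7138 at least 2-fold. The higher share was 50% under TMM, 61.8% under protein-coding scaling and 23.7% under mitochondrial scaling.

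The direct comparison of 3 µM with 1 µM in Z-138 asks which genes depended on the dose. EGR1 was higher at 3 µM, at 113 ± 10.2 against 62.7 ± 6.55 CPM, as were TEAD3, a Hippo pathway factor, WDR38, KANK3 and DEPP1, a FOXO-responsive gene, with log2 differences of 0.83 to 0.92. The largest falls were in KLHL25, an adaptor of a ubiquitin ligase (11 ± 1.84 to 1.95 ± 0.42 CPM, log2 difference −2.48 ± 0.21, adjusted p = 1.9e-13). Next were NRBF2, a gene of autophagy (−2.29 ± 0.14), UGCG, glucosylceramide synthase (−2.12 ± 0.11), ZNF670 (−2.09 ± 0.21) and RASGEF1B (−2.09 ± 0.08). HEXIM1 was lower at 3 µM by −0.73 ± 0.06, CCNT2, the P-TEFb cyclin T2 gene, by −1.35 ± 0.09, AXIN2 by −1.49 ± 0.22 and NFIL3 by −1.16 ± 0.09. CSNK1D was higher by 0.35 ± 0.07 (adjusted p = 0.00022), a call that ended under mitochondrial scaling (0.20), CSNK1E was lower by −0.42 ± 0.07 and CSNK1G3 by −1.04 ± 0.10.

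Of the lists, 5 were called at the preset correlation and each call ended with an estimated one. Immediate early genes were lower in 15 of 43 cases and higher in 5 (adjusted p = 0.0037, and adjusted p = 0.65 with an estimated correlation), RGS2 by −0.91 ± 0.09. P-TEFb genes were lower in 4 of 10 and higher in 2, with a median of 0.02, a mean of −0.23 and a test pointing down (adjusted p = 0.016, and adjusted p = 0.44 with an estimated correlation). Ribosomal protein genes were lower in 12 of 79 (median −0.08, adjusted p = 0.0074, and adjusted p = 0.82 with an estimated correlation), RPS20 by −0.34 ± 0.07. Nuclear oxidative phosphorylation genes were lower in 8 of 47 (median −0.08, adjusted p = 0.039, and adjusted p = 0.82 with an estimated correlation), UQCRFS1 by −0.36 ± 0.07. Ribosome biogenesis genes were higher in 16 of 56 and lower in 7, with a median of 0.14 that became −0.0056 under mitochondrial scaling (adjusted p = 0.027, and adjusted p = 0.65 with an estimated correlation). RIOK2, a kinase of small subunit maturation, went the other way, by −0.63 ± 0.10. Adjusted over the list alone these lists had 24, 7, 12, 8 and 30 called members, against 20, 6, 12, 8 and 23 over all genes. Among single genes, CD83 was lower by −1.19 ± 0.12, HIST1H1D higher by 0.42 ± 0.06, and MCL1 and BCL2 lower by −0.33 ± 0.05 and −0.34 ± 0.05. Under mitochondrial scaling the calls of RPS20 (−0.48), UQCRFS1 (−0.50), MCL1 (−0.47), BCL2 (−0.48), DEPP1 (0.83 to 0.69) and HIST1H1D (0.28) ended, the first 4 at larger differences than under TMM. CSNK1A1 (0.07 ± 0.06), PER1 (−0.02 ± 0.09), PER2 (0.23 ± 0.12), MYC (0.10 ± 0.06), CCND1 (0.08 ± 0.08), EIF4E (−0.0045 ± 0.09) and EIF4EBP1 (0.06 ± 0.11) did not pass the test.

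Of 17312 genes 2883 differed between the doses, 1422 higher and 1461 lower at 3 µM, and 320 of them by at least 2-fold (65 higher and 255 lower). The count fell to 881 under mitochondrial scaling, where 3.29% were higher against 49.3% under TMM. Log2 fold changes of the doses against the shared controls correlated across the tested genes with a Pearson r of 0.954 and a Spearman rho of 0.940. Unchanged groups simulated 20 times against the same controls gave a mean r of 0.421 (highest 0.435). The covariance was 3.04 against a simulated 0.0128, and the simulated groups shared a mean of 0.05 calls in the same direction (highest 1). Both doses raised 5851 genes and lowered 5812, where independent lists of these sizes would share 2395 and 2347, and 84 genes were called in opposite directions. Genes are not independent replicates, and part of the excess may come from the shared controls, since 3 controls do not divide into 2 groups of at least 2 libraries.

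In OCI-Ly10 the comparison asks whether 1 µM acted in a line of another lymphoma type. CSNK1D fell from 115 ± 3.63 to 33.4 ± 3.15 CPM (log2 fold change −1.77 ± 0.08, adjusted p = 3.1e-25). Of the 6 tested casein kinase 1 genes 5 fell (list adjusted p = 0.0095, and adjusted p = 0.11 with an estimated correlation). CSNK1G1 fell by 1.28 ± 0.10, CSNK1A1 by −0.33 ± 0.07 and CSNK1E by −0.19 ± 0.06 (adjusted p = 0.011). The CSNK1E call ended under protein-coding scaling (−0.09), the stricter filter (−0.11), the fit of the compared groups (−0.15) and without OCI-Ly10 1 µM replicate 3 (−0.15). Immediate early genes rose in 36 of 43 cases and fell in 4 (median 1.67, adjusted p = 1.8e-19, and adjusted p = 0.0725 with an estimated correlation). EGR1 (ENSG00000120738.7, chromosome 5, 138465490 to 138469315) went from 45.6 ± 1.82 to 745 ± 25.2 CPM. FOS and JUN, subunits of the AP-1 factor, rose 31.8-fold and 12.6-fold. MYC (ENSG00000136997.16, chromosome 8, 127735434 to 127741434) rose from 378 ± 12.4 to 943 ± 84.5 CPM (log2 fold change 1.32 ± 0.06, adjusted p = 3.2e-25). NF-κB targets went both ways, 14 of 33 higher and 15 lower (adjusted p = 0.82, median −0.02, mean 0.31). The cytokine genes TNF, CCL3 and CCL4 rose by 3.52 ± 0.08, 3.10 ± 0.10 and 2.71 ± 0.08, and CD83 fell by 1.90 ± 0.06. Opposite-strand exons cover 74.6% of those of CCL3.

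HEXIM1 rose by 2.26 ± 0.07, within a P-TEFb list that did not pass the test (5 of 10 higher, 3 lower, adjusted p = 0.19). Ribosome biogenesis genes fell in 38 of 56 cases and rose in 8 (median −0.38, adjusted p = 0.00026, and adjusted p = 0.11 with an estimated correlation), with RRN3 at −1.21 ± 0.09 and WDR75 at −1.03 ± 0.07. All 79 ribosomal protein genes rose, with a median of 0.38 that became −0.35 under mitochondrial scaling (adjusted p = 2.3e-11, and adjusted p = 0.39 with an estimated correlation). RPL36A rose by 1.84 ± 0.09 and RPS15A by 0.69 ± 0.06, the latter at −0.04 under that scaling. Translation initiation factors were higher in 16 of 48 and lower in 13 (adjusted p = 0.64). EIF4A1 (unshared exons) rose by 2.05 ± 0.12 and EIF4A2 by 0.85 ± 0.06. EIF4E (0.09 ± 0.08, adjusted p = 0.32) and EIF4EBP1 (0.25 ± 0.17, adjusted p = 0.20) did not pass the test. EIF4E was called higher under protein-coding (0.20) and lower under mitochondrial scaling (−0.60). The EIF4A2 call ended under the latter (0.14). MYC targets were higher in 12 of 39 cases and lower in 17 (adjusted p = 0.37), with a median of 0.02, a mean of −0.10 and a test pointing down.

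B-cell transcription factors fell in 15 of 24 cases and rose in 3 (median −0.55, adjusted p = 5.5e-06, and adjusted p = 0.014 with an estimated correlation), among them IKZF1, the Ikaros gene, from 874 ± 29.8 to 338 ± 1.81 CPM. BACH2, a B-cell repressor (ENSG00000112182.14, chromosome 6, 89926529 to 90296908), fell from 146 ± 7.05 to 11.4 ± 1.19 CPM (12.9-fold lower, adjusted p = 1.9e-33). G2/M and mitosis genes fell in 36 of 51 cases and rose in 2 (median −0.35, adjusted p = 2.7e-06, and adjusted p = 0.16 with an estimated correlation). G1/S and E2F genes fell in 29 of 50 and rose in 4 (median −0.24, adjusted p = 0.00026, and adjusted p = 0.11 with an estimated correlation). CCNF fell by 2.10 ± 0.08, E2F7 by −1.53 ± 0.09, HJURP, a centromere chaperone, by −1.75 ± 0.08 and SLBP, the histone stem-loop binding protein gene, by −1.05 ± 0.06. Replication histones were split, 9 of 43 higher and 15 lower (adjusted p = 0.78), HIST1H1A at 1.09 ± 0.13, a call that ended under mitochondrial scaling (0.37), and HIST1H1D at −0.64 ± 0.07. Of p53 targets 18 of 32 rose and 9 fell, with a median of 0.40 that became −0.32 under mitochondrial scaling (adjusted p = 0.042, and adjusted p = 0.38 with an estimated correlation). PMAIP1, the proapoptotic NOXA gene, rose by 1.95 ± 0.06, BTG2 by 1.21 ± 0.05, and TIGAR, a metabolic regulator, fell by 1.72 ± 0.08. The unfolded protein response fell in 19 of 29 cases and rose in 2 (median −0.31, adjusted p = 0.0026, and adjusted p = 0.11 with an estimated correlation). HERPUD1 stood at −0.85 ± 0.06 and DERL2 at −0.99 ± 0.09, both of degradation from the endoplasmic reticulum.

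Abundant non-coding RNAs rose in 8 of 9 cases (median 1.56, adjusted p = 5.1e-05, and adjusted p = 0.11 with an estimated correlation), NEAT1 3.82-fold and MALAT1 2.94-fold. Decay substrates and small nucleolar RNA hosts rose in 27 of 40 cases and fell in 9, with a median of 0.46 that became −0.27 under mitochondrial scaling (adjusted p = 3.4e-05, and adjusted p = 0.11 with an estimated correlation), SNHG3 2.91-fold. Mitochondrially encoded genes rose in 13 of 15 cases, with a median of 0.71 (adjusted p = 0.00059, and adjusted p = 0.44 with an estimated correlation). Nuclear oxidative phosphorylation genes rose in 28 of 47 and fell in 1, with a median of 0.23 that became −0.51 under mitochondrial scaling (adjusted p = 0.0067, and adjusted p = 0.51 with an estimated correlation). MT-ND2, itself part of that scaling, rose by 0.96 ± 0.09, and NDUFV2 rose by 1.09 ± 0.10, a call that ended under it (0.36). PER2 fell by 1.95 ± 0.10, BHLHE40 rose by 1.40 ± 0.06 and PER1 fell by 0.31 ± 0.13 (adjusted p = 0.036), in a clock list with 5 of 13 higher and 7 lower (adjusted p = 0.78). The PER1 call ended in 4 other settings (−0.29 to −0.21) and without OCI-Ly10 control replicate 2 (−0.23) or 1 µM replicate 3 (−0.25). Of 12 Wnt targets 3 rose and 3 fell (adjusted p = 0.82), and AXIN2, at 4 against 23 counts, fell by 2.09 ± 0.64 (adjusted p = 0.0042). BCL2 rose by 0.61 ± 0.05 but stood at −0.11 under mitochondrial scaling, and MCL1 (−0.03 ± 0.05, adjusted p = 0.62) did not pass the test but was called under that scaling (−0.75). CCND1, with 81 against 75 counts, stood at 0.47 ± 0.32 (adjusted p = 0.19), and without OCI-Ly10 1 µM replicate 1 it fell by 0.77. Without 1 µM replicate 2 or 3 it was called higher, by 0.94 and 0.78, as it was with a replicate block (0.60, adjusted p = 0.042). Adjusted over the list alone, counts of called members equalled those over all genes in the lists named for this line except ribosome biogenesis (47 against 46), unfolded protein response (22 against 21), p53 targets (29 against 27) and abundant non-coding RNAs (9 against 8).

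The other largest rises in OCI-Ly10 were WDR38 (49.4-fold), NALT1, RNF225, RNVU1-4, a U1-type small nuclear RNA gene, PHETA2, BTBD18 and LILRB1-AS1, 18.2-fold to 25.1-fold. Opposite-strand exons cover 64.1% of those of LILRB1-AS1. The other largest falls were WBP1L, MAP3K14, IFNLR1, a receptor of type III interferons, WDCP, ZNRF3, KLHL26 and IL2RA, an interleukin 2 receptor chain, 8.93-fold to 10.6-fold lower. The calls numbered 10830 of 17312, 5720 higher and 5110 lower, 5097 of them at least 2-fold. Among protein-coding genes 3124 were higher and 4748 lower, among long intergenic RNA genes 594 and 64, and among antisense genes 856 and 113. The higher share was 52.8% under TMM and 20.8% under mitochondrial scaling.

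**Figure D3:**
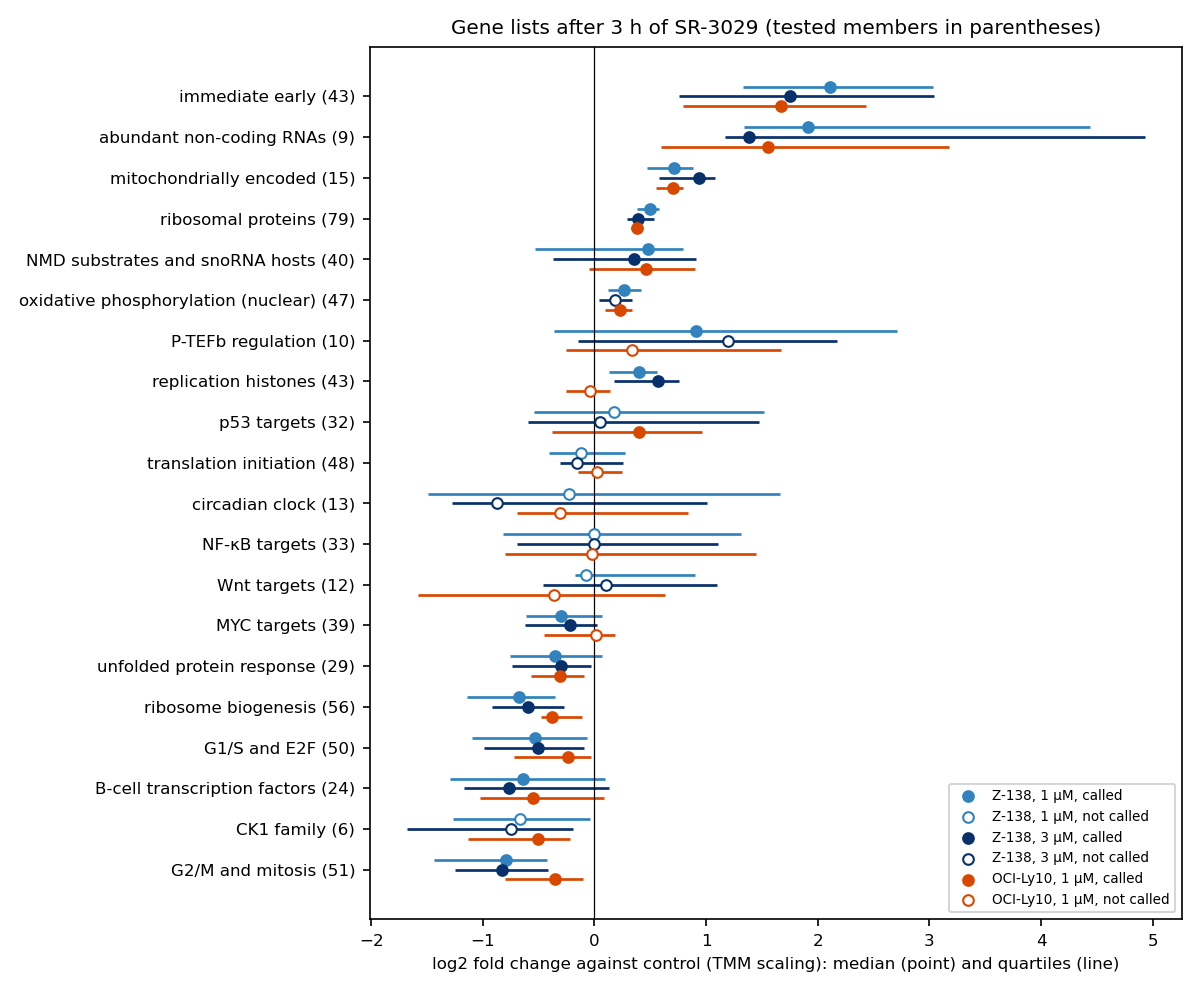
Log2 fold change against control (horizontal axis, TMM scaling) of 20 gene lists (vertical axis, tested members in parentheses), with medians as points and quartiles as lines, filled where the list was called by camera, for Z-138 at 1 µM and 3 µM and OCI-Ly10 at 1 µM. Immediate early genes had medians of 2.11, 1.75 and 1.67 and ribosome biogenesis genes −0.67, −0.60 and −0.38. Under mitochondrial scaling only the immediate early, abundant non-coding and, in Z-138, P-TEFb medians stayed above 0, and that of the mitochondrially encoded list is set near 0 by construction. Under protein-coding scaling medians at or below 0 moved above it for MYC targets (Z-138 3 µM), translation initiation (both Z-138 doses), Wnt targets (Z-138 1 µM), NF-κB targets (all 3) and replication histones (OCI-Ly10).

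The difference between the lines was tested directly as the OCI-Ly10 effect minus the Z-138 effect at 1 µM. BAMBI, which fell in Z-138, stood at 13.0 ± 2.61 and 18.3 ± 0.69 CPM in OCI-Ly10 control and treated libraries (difference of log2 fold change 5.44 ± 0.30, adjusted p = 2.2e-19). BCOR, a BCL6 co-repressor, went from 1.33 ± 0.36 to 12.5 ± 0.31 CPM in Z-138 and from 250 ± 6.78 to 82.1 ± 7.47 CPM in OCI-Ly10 (−4.82 ± 0.20, adjusted p = 6.7e-25). The other 8 genes with the largest differences had a group with 0 to 3 counts, so their fitted differences depend on the prior count. RHOB, a small GTPase gene, went from 682 to 4071 counts in Z-138 (ratio 10.2) and had 4 and 0 counts in OCI-Ly10. MIR222HG, a microRNA host gene, went from 469 to 2437 counts in OCI-Ly10 (ratio 6.69) and had 5 and 0 counts in Z-138. IGHJ4, an immunoglobulin heavy chain joining segment, had 0 and 39 counts in Z-138 (at least 22.3-fold higher) and CUEDC1 0 and 8 (at least 4.58-fold higher), where CUEDC1 went from 574 to 247 in OCI-Ly10. BTLA, a lymphocyte checkpoint receptor, went from 3 to 36 counts in Z-138 (ratio 20.6, 95% counting interval 6.51 to 105) and from 343 to 136 in OCI-Ly10. GTF2IRD1 went from 2150 to 621 counts in Z-138 and from 0 to 7 in OCI-Ly10, and LATS2 and ZNF607 had 0 and 2 counts in OCI-Ly10; without OCI-Ly10 1 µM replicate 1 their calls ended (2.83 and 2.59).

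MYC differed by 1.40 ± 0.08 (adjusted p = 3.1e-19), as under TMM it was called higher in OCI-Ly10 and not called in Z-138. As lists, cell cycle and ribosome biogenesis genes fell less in OCI-Ly10. The difference was positive for 32 of 51 G2/M and mitosis genes and negative for 1 (median 0.41, adjusted p = 5.4e-09, and adjusted p = 0.065 with an estimated correlation), and for 23 of 50 G1/S and E2F genes against 3 (median 0.20, adjusted p = 0.00041, and adjusted p = 0.065 with an estimated correlation). It was positive for 35 of 56 ribosome biogenesis genes against 2 (median 0.41, adjusted p = 1.3e-10, and adjusted p = 0.0024 with an estimated correlation) and for 15 of 39 MYC targets against 1 (median 0.19, adjusted p = 0.0058, and adjusted p = 0.38 with an estimated correlation). Examples were CKAP2 (1.04 ± 0.09) and KIF14 (1.10 ± 0.10), mitotic genes, E2F7 (1.49 ± 0.13), the ribosome biogenesis genes NOC3L (1.17 ± 0.11) and WDR36 (0.85 ± 0.09), and WDR74 (0.82 ± 0.10), which rose in both lines.

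Other lists were lower in OCI-Ly10 relative to Z-138. Immediate early genes had 19 of 43 negative and 4 positive differences (median −0.40, adjusted p = 4.7e-06, and adjusted p = 0.16 with an estimated correlation). BTG2 stood at −2.21 ± 0.08, ATF3, a stress-induced factor, at −2.27 ± 0.12 and PIM1, a kinase gene, at −1.85 ± 0.09. The ATF4 stress response had 15 of 34 negative and 3 positive (median −0.24, adjusted p = 9.2e-06, and adjusted p = 0.065 with an estimated correlation), with CHAC1, a glutathione-degrading enzyme, at −2.81 ± 0.23. P-TEFb genes had 5 of 10 negative and 1 positive (median −0.57, adjusted p = 0.0055, and adjusted p = 0.065 with an estimated correlation), with HEXIM1 at −0.79 ± 0.09. BCL2 family genes had 6 of 15 negative (median −0.40, adjusted p = 0.0020, and adjusted p = 0.058 with an estimated correlation), among them BBC3, the proapoptotic PUMA gene, at −1.32 ± 0.12, MCL1 at −0.44 ± 0.07 and BCL2 at −0.40 ± 0.07. Replication histones had 34 of 43 negative and 1 positive (median −0.45, adjusted p = 3.2e-12, and adjusted p = 0.39 with an estimated correlation), HIST1H1D at −0.82 ± 0.09 and HIST1H2BG at −0.74 ± 0.09. Abundant non-coding RNAs had 5 of 9 negative and 1 positive (median −1.27, adjusted p = 0.0080, and adjusted p = 0.38 with an estimated correlation), NEAT1 at −0.68 ± 0.08. Ribosomal protein genes had 15 of 79 negative and 2 positive, with a median of −0.10 that became 0.01 under mitochondrial scaling (adjusted p = 0.0055, and adjusted p = 0.80 with an estimated correlation), RPS23 at −0.62 ± 0.08.

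In the kinase family CSNK1D differed by −0.36 ± 0.10 (adjusted p = 0.0047), CSNK1E by −0.49 ± 0.10 and CSNK1G1 by 1.08 ± 0.16. The list did not pass the test (adjusted p = 0.83, with a median of 0.02, a mean of 0.07 and a test pointing down). BHLHE40 (−0.90 ± 0.09), CD83 (−1.71 ± 0.11), NFKBIA, the NF-κB inhibitor gene (1.08 ± 0.09), EIF4E (0.61 ± 0.11), EIF4EBP1 (0.58 ± 0.19) and AXIN2 (−1.92 ± 0.67, adjusted p = 0.021) also differed. The AXIN2 call ended under mitochondrial scaling (−1.80) and without OCI-Ly10 control replicate 2 (−1.72) or 1 µM replicate 1 (−1.82) or 2 (−1.60), and the EIF4EBP1 call in 4 settings (0.44 to 0.74). CSNK1A1 (0.17 ± 0.09), PER1 (−0.33 ± 0.16, adjusted p = 0.11), PER2 (0.13 ± 0.15) and CCND1 (0.51 ± 0.33) did not pass the test. CCND1 stood at −0.73 without OCI-Ly10 1 µM replicate 1 and was called without replicate 2 (0.99) or 3 (0.82). PER1 passed it in 5 other settings (−0.47 to −0.39) and without Z-138 control replicate 3 (−0.43) or Z-138 1 µM replicate 1 (−0.41). Under mitochondrial scaling the calls of CSNK1D (−0.27), CSNK1E (−0.40), MCL1 (−0.31), BCL2 (−0.28), RPS23 (−0.52) and NEAT1 (−0.57) ended, with the direction kept. Of 17312 genes 6026 differed between the lines, 3561 with a higher and 2465 with a lower value in OCI-Ly10. Of them 2198 differed by at least 2-fold, with the direction turned, 739 higher and 1459 lower. Mitochondrial scaling gave 3163. The positive share was 59.1% under TMM, 48.0% with DESeq2 size factors, 47.5% in the DESeq2 Wald test and 42.4% under protein-coding scaling. Adjusted over the list alone, the 11 lists called here had 37 (G2/M), 26 (G1/S), 41 (ribosome biogenesis), 16 (MYC), 27 (immediate early), 20 (ATF4), 7 (P-TEFb), 6 (BCL2 family), 38 (histones), 7 (non-coding) and 13 (ribosomal protein) members called, against 33, 26, 37, 16, 23, 18, 6, 6, 35, 6 and 17 over all genes.

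**Figure D4:**
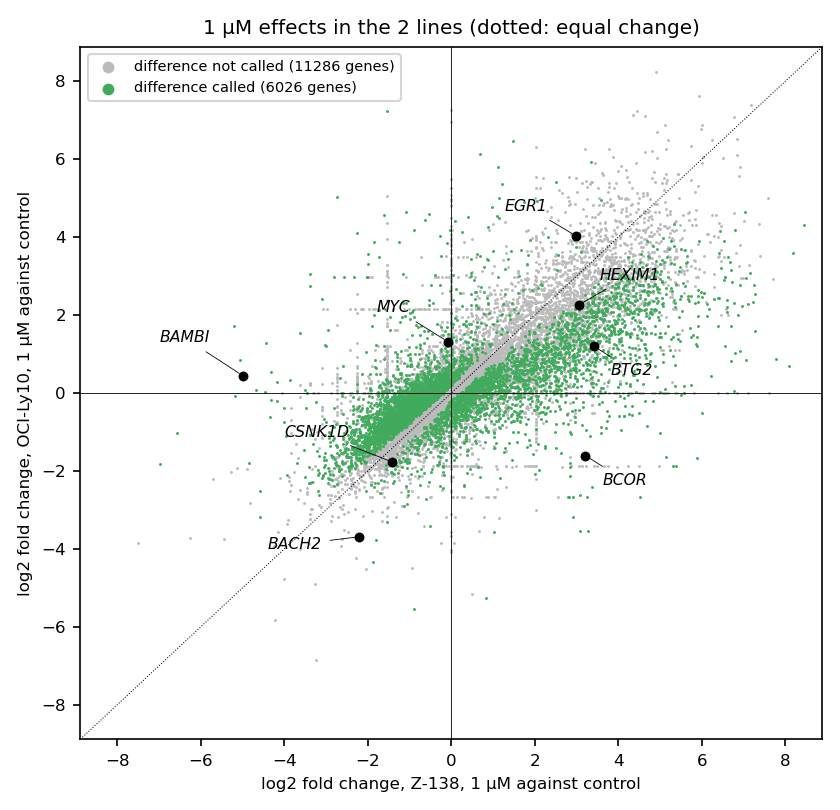
Log2 fold change at 1 µM against control in Z-138 (horizontal axis) and OCI-Ly10 (vertical axis), a point per tested gene, green for the 6026 genes whose effects differed between the lines and grey for the other 11286, with 8 genes named and a dotted line of equal change. Most genes lay in the quadrants of the same sign (Pearson r of 0.741 across genes), BAMBI and BCOR in opposite ones.

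Across the tested genes the 1 µM effects of the lines, which share no library, correlated with a Pearson r of 0.741 and a Spearman rho of 0.758, and 78.3% had the same sign. The slope of the OCI-Ly10 on the Z-138 values was 0.56. Both lines raised 4450 genes, where independent lists of these sizes would share 2145, and lowered 4251 (1880 for independent lists), and 395 genes were called in opposite directions (4021 for independent lists). Genes are not independent replicates, so no p-value is given.

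Averaged over both lines, 6 treated against 6 control libraries, CSNK1D was lower by −1.59 ± 0.05 (adjusted p = 2.1e-31), PER2 by −2.02 ± 0.07, CSNK1A1 by −0.41 ± 0.05 and AXIN2 by −1.13 ± 0.33. HEXIM1 was higher by 2.66 ± 0.05 (adjusted p = 1.6e-41). MYC (0.62 ± 0.04), BCL2 (0.81 ± 0.04) and MCL1 (0.19 ± 0.04) were higher under TMM; under mitochondrial scaling MYC stood at −0.17 and MCL1 at −0.59, and the BCL2 call ended (0.03). EIF4E was lower by −0.21 ± 0.06 (adjusted p = 0.00094), a call that ended under protein-coding scaling (−0.04) and the stricter filter (−0.08). CSNK1E (0.06 ± 0.05, adjusted p = 0.27), PER1 (−0.14 ± 0.08, adjusted p = 0.0975), CCND1 (0.22 ± 0.16, adjusted p = 0.23) and EIF4EBP1 (−0.05 ± 0.10, adjusted p = 0.69) did not pass the test. CCND1 stood at −0.41 without OCI-Ly10 1 µM replicate 1 and was called without replicate 2 (0.45) or 3 (0.37). PER1 was called without Z-138 control replicate 1 (−0.19) or OCI-Ly10 control replicate 3 (−0.18) and with no filter (−0.18). CSNK1E was called higher in 4 settings (0.12 to 0.23), and CCND1 under protein-coding scaling (0.39). Mitochondrial scaling called all 4 lower (CSNK1E −0.73, PER1 −0.94, CCND1 −0.53, EIF4EBP1 −0.80). Of 17312 genes 12689 were called, 6535 higher and 6154 lower, 6114 at least 2-fold, and the higher share of 51.5% became 24.9% under mitochondrial scaling.

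Camera called 12 lists for the mean effect, and each call ended with an estimated correlation. Immediate early genes rose in 38 of 43 cases and fell in 3 (adjusted p = 1.6e-16, and adjusted p = 0.079 with an estimated correlation). Ribosomal protein genes rose in 79 of 79, though with a median below 0 under mitochondrial scaling (0.44 and −0.35; adjusted p = 6.3e-14, and adjusted p = 0.38 with an estimated correlation). Abundant non-coding RNAs rose in 9 of 9 (adjusted p = 3.9e-05, and adjusted p = 0.12 with an estimated correlation). Genes of G2/M and mitosis (45 of 51), G1/S and E2F (36 of 50), ribosome biogenesis (44 of 56), B-cell transcription factors (17 of 24), the unfolded protein response (20 of 29) and the casein kinase 1 family (4 of 6) fell. They had adjusted p = 2.5e-10, 4.6e-06, 8.1e-08, 0.00024, 0.0032 and 0.037 in that order, and adjusted p = 0.12, 0.083, 0.079, 0.056, 0.12 and 0.12 with an estimated correlation. Mitochondrially encoded genes (13 of 15), nuclear oxidative phosphorylation genes (36 of 47) and decay substrates with small nucleolar RNA hosts (27 of 40) rose, with medians of 0.72, 0.25 and 0.43, of which the last 2 became −0.53 and −0.36 under mitochondrial scaling (adjusted p = 0.00046, 0.0025 and 0.0016, and adjusted p = 0.45, 0.46 and 0.16 with an estimated correlation). Adjusted over the list alone, 43 G1/S and E2F genes and 15 mitochondrially encoded genes were called, against 42 and 14 over all genes, and the other 10 of these lists had the same counts both ways.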

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

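Of the tests in this part, the comparisons of ribosomal protein, oxidative phosphorylation and mitochondrially encoded genes, mitochondrial scaling and the count of non-coding genes far from expressed genes were chosen only after the result was seen.

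What drew attention here was a difference between the lines, the OCI-Ly10 effect minus the Z-138 effect at 1 µM on the log2 scale, tested directly. It passed the threshold for 6026 genes and 11 lists, of which 1, ribosome biogenesis, stayed called with an estimated correlation. List medians of the difference were 0.41 for G2/M and mitosis, 0.41 for ribosome biogenesis, 0.20 for G1/S and E2F and 0.19 for MYC targets. They were −1.27 for abundant non-coding RNAs, −0.57 for P-TEFb, −0.45 for replication histones, −0.40 for immediate early genes, −0.40 for the BCL2 family, −0.24 for the ATF4 stress response and −0.097 for ribosomal proteins, the last at 0.01 under mitochondrial scaling. Except for the ATF4 stress response, each list's difference under TMM had the sign opposite to its median in Z-138 at 1 µM. Across genes the slope of the OCI-Ly10 on the Z-138 values was 0.56. A smaller effect in OCI-Ly10 across genes was thus not told apart from differences particular to these lists. Of 115 named genes tested in both lines 86 differed, and 21 of the 115 had opposite signs, called or not. Many of these genes were named for large effects or differences in these data, which raises such shares. Of all 17312 tested genes 34.8% differed.

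Higher values in OCI-Ly10 were found for cell cycle and ribosome biogenesis genes: E2F7 (1.49), KIF14 (1.10), CKAP2 (1.04), EXO1 (0.75), CCNF (0.74), CDC25A (0.37), NOC3L (1.17), WDR36 (0.85), WDR74 (0.82), WDR75 (0.70), NOL11 (0.74), POLR1B (0.73), WDR43 (0.68) and RRN3 (0.555). They were also found for BAMBI (5.44), MYC (1.40), EGR1 (1.051), NFKBIA (1.08), CREB3L2 (1.13), DNAJC3 (0.69), CSNK1G1 (1.08), IKZF3 (0.53), IRF4 (0.45), REL (0.52), TIGAR (0.51), EIF4E (0.61), EIF4EBP1 (0.58), EIF5 (0.63), EIF4A1 (0.45), EIF4A2 (0.23) and MALAT1 (0.22), and for genes that fell more in Z-138: KIAA0355 (2.06), KLHDC10 (1.90), KIAA0040 (1.5), KLHL26 (1.405), PHLPP2 (1.36) and GTF2E1 (1.09).

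Called lower in OCI-Ly10 were CHAC1 (−2.81), ATF3 (−2.27), BTG2 (−2.21) and GADD45A (−1.92), but not the immediate early genes EGR1, IER2, JUN or FOS. Others were BCOR (−4.82), HSPB7 (−3.235), PIM1 (−1.85), SERTAD1 (−1.36), BBC3 (−1.325), WBP1L (−2.89), BACH2 (−1.49), CD83 (−1.71), FZD7 (−1.48), NFIL3 (−1.47), HERPUD1 (−0.95), BHLHE40 (−0.90), HEXIM1 (−0.79), CCL4 (−0.70), CSNK1E (−0.49), CSNK1D (−0.36), MCL1 (−0.44), BCL2 (−0.40) and IKZF1 (−0.22). Non-coding RNAs and genes of ribosomal proteins, histones and mitochondria with lower values were LINC02028 (−3.58), RNU5A-1 (−2.23), RNU5B-1 (−2.14), ADAMTSL4-AS1 (−1.56), MT-ATP8 (−1.30), MT-ND4L (−0.45), RPL41 (−1.02), RPS23 (−0.62), HIST1H1D (−0.82), HIST1H2BG (−0.74), HIST1H3A (−0.70), NEAT1 (−0.68), SNHG3 (−0.48) and NDUFV2 (−0.65). The remaining differences rest on a group with 0 to 4 counts in 1 of the lines, so their size depends on the prior count: MIR222HG (6.13), LATS2 (5.795), GTF2IRD1 (5.73), ZNF607 (5.55), TNF (3.775), RHOB (−6.83), IGHJ4 (−5.85), CUEDC1 (−5.52), BTLA (−5.03), NAALADL1 (−4.15), NALT1 (−2.37) and AXIN2 (−1.92).

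Treated and control libraries were relabelled within the lines to test the mean effect. The splits argue against chance in how these libraries fell into groups, but 1 of 100 is the smallest share they can give. Chance between cultures is not covered, since the replicates may be technical. Only 1 of 100 such splits, the real one, gave as many genes, with 12689 against 9922 in the highest other. For the line difference the same splits (1 of 100 with as many, 6026 against 5115 in the highest other) decide nothing. They remove the treatment effect itself, and mirroring the labels of 1 line, which keeps it, turns the difference into the mean effect with its 12689 genes. The 3 against 3 comparisons allow 10 splits, too few for a share under 0.05. There the real split was the only 1 of 10 with as many genes, 12861 against 0 in the highest other for Z-138 at 1 µM, 12765 against 0 at 3 µM, 2883 against 3 between the doses and 10830 against 0 for OCI-Ly10.

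The first pattern weighed is the rise of rarely counted and non-coding genes in treated libraries. Genomic DNA would spread reads evenly, but genes silent in controls within 20 kb downstream of an expressed gene had at least 3.54 times the count density of those over 100 kb from any in each of the 9 treated libraries (7.10 to 8.63 in Z-138), which argues against DNA as the whole source. Intronic reads of surrounding genes stay open. Non-coding genes over 20 kb from any expressed protein-coding gene had median log2 fold changes of at least 0.778 (lower quartile 0). At least 250 of them rose (34 of 562 fell in OCI-Ly10), but genes under 5 CPM or non-coding ones may surround them. Reads running past the end of the upstream gene stay open, since the density downstream of a same-strand gene was 0.786 to 1.115 times that upstream of one in Z-138 and 1.39 to 1.91 times in OCI-Ly10. Changed transcription or decay of these RNAs under the inhibitor remains an untested explanation.

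The second pattern is that long genes fell and short genes rose, though the longest of 5 groups fell less (median −0.46 in Z-138 at 1 µM) than the one before it (−0.61). Exonic length bias of the libraries is argued against as the whole cause, since the Spearman correlation of log2 fold change with genomic span at fixed exonic length was −0.175 in OCI-Ly10, −0.246 in Z-138 at 1 µM and −0.220 at 3 µM. Low counts are argued against too, since among genes over the median abundance the Spearman correlation with span was −0.290 in OCI-Ly10 and −0.455 and −0.392 in Z-138. A slower release or elongation of RNA polymerase II in 3 h might give such a pattern, but no test of elongation was made.

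The third pattern is the rise of ribosomal protein mRNAs beside other stable RNAs. If a single scaling factor for stable RNAs were the whole source, ribosomal protein, nuclear oxidative phosphorylation and mitochondrially encoded genes would move alike, but the interquartile ranges were apart in 5 of 9 pairs, by up to 0.241, each time with the mitochondrially encoded genes. For the 2 nuclear lists alone a common factor stays open, since their ranges overlapped in all 3 comparisons (largest gap −0.00944). A loss of total short-lived RNA, with stable RNA unchanged, could still give part of the rise: under mitochondrial scaling the ribosomal protein medians were −0.34, −0.58 and −0.35 (Z-138 1 µM, Z-138 3 µM, OCI-Ly10).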

How the results depend on the processing

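Of the settings in this part, mitochondrial scaling and thinning were chosen only after the result was seen.

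The counts give levels relative to the other genes of a library, so a change in RNA per cell was not measured, and groups of 3 limit the precision. Depth limits the rarer genes: with every library thinned to the smallest total 11202, 11012, 2259, 9592, 4702 and 11223 genes passed for Z-138 at 1 µM, at 3 µM, between the doses, OCI-Ly10, the line difference and the mean effect. Counts of called genes stayed within 1.5 times the main count under all scalings, filters and tests except those given here. A minimum absolute log2 fold change of 1 left 7272, 7138, 320, 5097, 2198 and 6114 in the same order, fewer by construction. Mitochondrial scaling left 881 between the doses and 3163 for the line difference. The cause was not tested, but the mitochondrial share varied between replicates (4.58% to 5.67% at 3 µM). Leaving out each library gave 12580 to 13325, 12355 to 13222, 1996 to 3281, 10189 to 11041, 5463 to 5976 and 12634 to 12965 genes in the same order of comparisons, and 12 to 14, 11 to 13, 5 to 6, 12 to 13, 10 to 11 and 12 to 13 lists. An estimated correlation left 4, 5, 0, 1, 1 and 0 called lists against 14, 12, 5, 13, 11 and 12, and fry, a test of each list against no change, called 26, 29, 8, 25, 15 and 25. A replicate block gave 12801, 12713, 2778, 10633, 5931 and 12575 genes and 12, 11, 4, 12, 11 and 11 lists. Of the named genes it added CCND1 in OCI-Ly10 (0.60, adjusted p = 0.042) and changed no other call. The replicates share only a number: of 12 same-numbered pairs 0 had a residual correlation over 0.1 (−0.040 to 0.039), and 3 libraries correlated best with their own number. Under the stricter filter the correlation of effects was 0.791 between the lines (0.741 over all tested genes) and 0.960 between the doses (0.954).

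The 258 results of 135 named genes gave 6937 values over the other settings: 6694 on the same side of the threshold with the same sign, 112 that lost a call, 46 that gained one and 85 of opposite sign, called or not (20 of these without a library). AXIN2 in OCI-Ly10 was not tested in the fit of the compared groups. Of the called results 3 turned sign in a setting that also called them, all under mitochondrial scaling (MCL1 in Z-138 at 1 µM and in the mean effect, CSNK1E in Z-138 at 1 µM). Values of opposite sign follow, and the cause was not tested. Mitochondrial scaling gave, for Z-138 at 1 µM MCL1 −0.44, PER1 −0.81, CSNK1E −0.53, COX7B −0.26, and for Z-138 at 3 µM MCL1 −0.91, MYC −0.96, CCND1 −0.93, BCL2 −0.32, and for the dose comparison CSNK1A1 −0.075, EIF4EBP1 −0.082, MYC −0.042, CCND1 −0.062, and for OCI-Ly10 EIF4E −0.60, EIF4EBP1 −0.43, CCND1 −0.20, RPS15A −0.037, BCL2 −0.11, and for the mean effect MCL1 −0.59, MYC −0.17, CCND1 −0.53, CSNK1E −0.73. Protein-coding scaling gave, for Z-138 at 1 µM MYC 0.16, CCND1 0.21, AXIN2 0.076, and for Z-138 at 3 µM PER1 0.24, CSNK1E 0.13, and for OCI-Ly10 MCL1 0.071, and for the line difference PER2 −0.011, and for the mean effect EIF4EBP1 0.13, PER1 0.029. The stricter filter gave, for Z-138 at 1 µM MYC 0.098, CCND1 0.15, AXIN2 0.011, and for Z-138 at 3 µM PER1 0.17, CSNK1E 0.063, and for OCI-Ly10 MCL1 0.042, and for the mean effect EIF4EBP1 0.081. DESeq2 size factors gave, for Z-138 at 1 µM MYC 0.028, CCND1 0.075, and for Z-138 at 3 µM PER1 0.11, and for the mean effect EIF4EBP1 0.017. The DESeq2 Wald test gave, for Z-138 at 1 µM MYC 0.028, CCND1 0.075, and for Z-138 at 3 µM PER1 0.11, and for the mean effect EIF4EBP1 0.020. Thinning gave, for Z-138 at 1 µM MYC 0.019, CCND1 0.077, and for Z-138 at 3 µM PER1 0.12, and for the dose comparison PER1 0.011, and for OCI-Ly10 MCL1 0.0019, and for the mean effect EIF4EBP1 0.032. Fits of the compared groups gave, for Z-138 at 1 µM MYC 0.011, CCND1 0.058, and for Z-138 at 3 µM PER1 0.061, and for OCI-Ly10 MCL1 0.0055. Library size alone gave, for Z-138 at 1 µM CCND1 0.038, and for Z-138 at 3 µM PER1 0.079, and for the dose comparison EIF4E 0.0041. Fits with no filter gave, for Z-138 at 3 µM PER1 0.029, and for the dose comparison EIF4E 0.033, PER1 0.016. limma-voom gave, for Z-138 at 3 µM PER1 0.0065, and for OCI-Ly10 CCND1 −0.0015, and for the mean effect CCND1 −0.018. The replicate block gave, for Z-138 at 3 µM PER1 0.0041. Ranges without each library that crossed 0 were −0.066 to 0.12 for PER1 in Z-138 at 1 µM, −0.031 to 0.047 for MYC and −0.087 to 0.0998 for PER1 at 3 µM. Between the doses they were −0.022 to 0.0094 for EIF4E, −0.024 to 0.13 for EIF4EBP1 and −0.11 to 0.044 for PER1. In OCI-Ly10 they were −0.059 to 0.0035 for MCL1 and −0.77 to 0.94 for CCND1, and for CCND1 −0.73 to 0.99 in the line difference and −0.41 to 0.45 in the mean effect.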

Other observations

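The zinc finger genes described here and their tests were chosen only after the result was seen.

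Protein-coding genes whose symbol begins with ZNF, mostly C2H2 zinc finger transcription factors, fell more often than other genes. Of 416 tested, 293 fell and 47 rose in Z-138 at 1 µM (median log2 fold change −0.94), 309 fell and 38 rose at 3 µM (median −1.07), and 214 fell and 40 rose in OCI-Ly10 (median −0.56). The shares that fell were 70.4%, 74.3% and 51.4%, against 45.9%, 45.8% and 37.1% of the 12228 other protein-coding genes. Other protein-coding genes matched in 5 groups of genomic span and 5 of abundance had medians of −0.22, −0.23 and −0.099. The camera p-values were 7.0e-12, 1.2e-14 and 1.2e-08 (unadjusted), and 7.4e-05, 2.1e-05 and 0.0035 with an estimated correlation. The medians stayed below 0 under protein-coding scaling (−0.70, −0.83 and −0.45) and mitochondrial scaling (−1.77, −2.03 and −1.27).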
